A study of Rattus norvegicus with 6 samples.

How the data were processed

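RNA-seq was done on 6 libraries of rat subchondral bone. Per the labels' protocols, RNA was isolated with an RNeasy kit and libraries were built with a SMARTER mRNA-Seq kit. The deposited data are a table with a count column and an FPKM column for each library. The counts are whole numbers per gene as the authors deposited them, with no normalization. The FPKM values were computed by the authors, per the file headers, as fragments per kilobase of transcript scaled to library size, and were not brought to a common sum: their totals were 811992 to 1047310 per library. The aligner, the counting tool and their versions are not given in the sources used here. Per the submitters' processing notes the genome builds are GRCm38 and mm10, which are mouse builds, while the row IDs are rat Ensembl IDs, so the build behind the values is not settled and no coordinates are given.

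The table held 30610 rows. Of these, 10 held no values and were left out. The other 30600 were 22050 rat Ensembl genes and 8550 loci outside the annotation, which carry no gene name. Gene names were those of the table, where 25 names had been turned into dates by spreadsheet software and could not be matched. Where a list gene had no row by name, the Ensembl IDs of the reference table were tried, and 0 were matched. Of 399 entries in 35 gene lists, 381 had a row by name and 18 had none. The reference table of the assembly GRCr8 served only for which genes neighbour each other, with 16613 genes placed by symbol. All value columns were used.

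The labels give no temperature, treatment or group for any library. All 6 were therefore kept unassigned. Values are given per library or as a range and median, no groups were compared, no library was tested as an outlier of a group, and no group test treats the libraries as replicates. The list correlations below take the 6 libraries as exchangeable, and whether they came from separate animals is not given in the sources used here. Total counts of 39990624 to 59200981 set the precision. A count of 0 allows up to 3 counts, and intervals for shares of counts are exact 95% binomial intervals (Clopper-Pearson). Both cover counting error only.

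The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 20 genes with the highest median FPKM, the 20 with the largest range of log2(FPKM + 1) among genes with a median of at least 1 FPKM, up to 4 members of each list with the highest medians, and every member of the cold-inducible, cold sensor, thermogenic, heat shock, cytokine and matrix protease lists. Other genes named were chosen after their values were seen: Epx, Il5ra, Ccr3 and the basophil and mast cell list including Prss34, as well as Alox15, Postn, Col3a1, Gal, Ikzf1, Tnfsf11, Tnfrsf11b and the genes next to the globin clusters.

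The level of a list was the median over its members of log2(FPKM + 1), set against 10000 random lists of the same size drawn from expressed genes. Expressed genes are the 11625 annotated genes with a median of at least 1 FPKM. The score of a list in a library was the mean over its expressed members of log2(FPKM + 1) minus the gene's median over the libraries. The range of the score over the libraries was compared with that of 10000 random lists of the same size, matched on median FPKM in 10 bins. This is a 1-sided permutation test over genes, whose smallest p is 0.0001, with Benjamini-Hochberg adjustment over the 31 lists with at least 3 expressed members and a threshold of 0.05. In the other 4 lists (cold sensors, thermogenic, sex-linked and absent tissues) fewer members were expressed. Fold differences on the log2(FPKM + 1) scale understate those of low genes. A gene was called variable at a range of 2 or more. Scores of bone lists were correlated with those of marrow and soft tissue lists over the 6 libraries, with exact permutation tests over all 720 pairings. Gene length was taken from the deposited counts and FPKM, as the length implied by their ratio, and the length correction removed each library's median in 20 length bins. Variable neighbours were sought with the median range of 11 neighbouring genes and 200 random gene orders.

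Alternatives were pseudocounts of 0.1, other FPKM minimums, TMM factors from edgeR 4.0.16 and median-ratio factors applied to FPKM, values rescaled to a common sum, median scores and leaving out each library. Correction for gene length, leaving out the genes next to the globin clusters, and the eosinophil list and basophil and mast cell list were added after the data were seen. On simulated counts for 11588 genes with the means and library sizes of these data and a dispersion of 0.05, lists of 10 genes changed 1.5-fold, 2-fold or 4-fold in 1 library passed at an unadjusted 0.05 in 100% of 5 lists each. At 1.25-fold 80% of 5 lists passed, and 4% of 200 unchanged lists did. The simulated genes varied independently, without the shifts between libraries and the length trend of these data. In these data 95% of matched random lists had ranges up to 0.68 for the heat shock list and 0.92 for the cold-inducible list. In the main setting a list with a range under its value does not pass, even before adjustment. Changes of 1.25-fold or 1.5-fold may therefore pass less often here than in the simulation. The cold-inducible list also has only 5 members, against 10 in each simulated list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.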

Results

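RNA from rat subchondral bone, the bone that carries the cartilage of the knee joint, was sequenced in 6 libraries titled S10, S12, S13, S20, S21 and S23. The series set out to find molecules that link cold and arthritis by comparing rats held at low temperature with rats held at normal temperature. The labels used here tie none of the 6 libraries to a temperature, so no library was placed in a group and no cold effect was tested. The account below gives the level of each gene or gene list in the tissue and its spread over the libraries. Whether the libraries came from separate animals is not given in the sources used here. Total counts were 39990624 in S10, 44194710 in S12, 54027226 in S13, 40728543 in S20, 59200981 in S21 and 46272709 in S23. Rows at 1 FPKM (fragments per kilobase of transcript, scaled to library size) or more numbered from 11551 in S10 to 13252 in S12, with a median of 12730.5. These counts include the loci outside the annotation.

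Transcripts of red cells and granulocytes dominated the bone. The alpha-globin gene Hba-a1 (ENSRNOG00000029886) reached 75751 FPKM in S23 and 215071 FPKM in S10, Hba-a2 ranged from 38952 to 108752 FPKM, and the beta-globin gene Hbb (ENSRNOG00000058105) from 43778 to 108045 FPKM, each lowest in S23 and highest in S10. The 4 rows named Hba-a1, Hba-a2, Hba-a3 and Hbb took 27.6% of all counts in S10, 18.9% in S12, 20.8% in S13, 19.3% in S20, 19.8% in S21 and 10.4% in S23. At these depths both bounds of each share's 95% exact binomial interval (Clopper-Pearson) lay within 0.1 percentage points of it, which covers counting error only. The next rows, LOC103694857 and LOC103694855, had medians of 23000 and 22307 FPKM and were also lowest in S23 and highest in S10, but carry only locus names and were not counted as globins. Among the 20 genes with the highest median FPKM, those of granulocytes came after these rows: S100a9 and S100a8, which encode the subunits of calprotectin, had medians of 19361 and 13504 FPKM, and the defensin-type peptide genes Np4, Defa5 and RatNP-3b had medians of 9183, 8080 and 5665 FPKM. Lyz2, the lysozyme of myeloid cells, had a median of 7399 FPKM, and the mitochondrially encoded Mt-co1, Mt-co2, Mt-co3, Mt-atp6 and Mt-atp8 had medians from 2969 to 4794 FPKM. The 10 most abundant rows held 36.3% (S23) to 54.4% (S10) of all FPKM, with a median of 46.7% over the libraries. Without the 4 named globin rows, and with the 2 locus-named rows kept, that median was 22.5%.

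Genes of bone-forming cells were strongly expressed in every library. All 14 osteoblast genes had a median of at least 1 FPKM, and the median level of the list, 4.71 on the log2(FPKM + 1) scale, exceeded that of 98.95% of 10000 random lists of expressed genes. Spp1 (osteopontin) ranged from 396 to 754 FPKM, Sparc (osteonectin) from 410 to 632 FPKM, Bglap (osteocalcin) from 255 to 610 FPKM, and Col1a1 (ENSRNOG00000003897), a chain of type I collagen, from 166 to 362 FPKM. Osteocyte genes were lower: the list's level was 1.55, above 0.19% of random lists, and 7 of 9 members reached a median of 1 FPKM, led by Mepe at 38.6 FPKM and Dmp1 at 38.5 FPKM. Sost, which encodes the Wnt inhibitor sclerostin, had a median of 7.20 FPKM and its highest value, 10.7 FPKM, in S12. Genes of bone-resorbing osteoclasts had a level of 3.29, above 47.3% of random lists, with medians of 1042 FPKM for Car2 (also a red cell gene), 407 FPKM for the collagen-cleaving cathepsin Ctsk, 262 FPKM for Acp5 and 184 FPKM for Mmp9 (also a neutrophil gene). Cartilage genes were present as well: 13 of 16 chondrocyte genes passed a median of 1 FPKM, with Col2a1 at 59.1 to 152 FPKM and Comp at 23.8 to 41.3 FPKM, and among hypertrophic cartilage genes Mmp13 ranged from 103 to 179 FPKM and Col10a1 had 8.06 FPKM in S10 and a median of 19.1 FPKM. Lum, Thy1, Dcn and Fmod, the highest of the tendon and synovial fibroblast list, had medians of 80.7, 42.1, 38.9 and 9.53 FPKM.

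Marrow lineages other than the red cells and granulocytes were also measured. The monocyte and macrophage list, with a level of 5.57, exceeded 99.88% of random lists, and C1qa, C1qb and C1qc, the chains of complement C1q made by macrophages, had medians of 169, 98.3 and 120 FPKM. The proliferation list exceeded 99.89% of random lists, with Birc5, Cdk1, Rrm2 and Ccna2 at medians of 90.8, 90.7, 75.4 and 71.8 FPKM. The megakaryocyte genes Pf4 and Ppbp had medians of 855 and 252 FPKM. The B cell list stood above 71.05% of random lists, led by Cd74 at 350 FPKM and Cd79b at 51.6 FPKM. T and NK cell genes and endothelial genes were lower, above 5.16% and 11.29% of random lists. In the T and NK cell list the highest medians were those of Nkg7 (240 FPKM) and Cd4 (19.6 FPKM), and in the endothelial list those of Egfl7 (12.8 FPKM) and Tie1 (10.4 FPKM). Markers of liver, brain and gut served as absent tissues, and 7 of 8 had a median under 1 FPKM. The exception was Gfap at 1.27 to 5.52 FPKM. Among Y-linked genes Eif2s3y ranged from 34.9 to 52.8 FPKM and Kdm5d from 2.69 to 8.49 FPKM, while Ddx3y stayed at or under 0.0252 FPKM and Usp9y had 0 counts in all 6 libraries.

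The cold-inducible genes were abundant, and their spread over the libraries did not pass the test. Rbm3 (ENSRNOG00000005387), an RNA-binding protein gene known to rise in cooled cells, ranged from 299 FPKM in S12 to 437 FPKM in S23, and its relative Cirbp (ENSRNOG00000015999) from 18.3 FPKM in S13 to 29.2 FPKM in S21. Srsf5, Rtn3 and Sgk1 had medians of 245, 76.7 and 19.3 FPKM. Sgk1 is also in the glucocorticoid response list, and membership of the cold-inducible list does not mean that cold raises a gene in this tissue. All 5 members varied by less than 1 log2 unit in the deposited values. The list score, the mean over members of log2(FPKM + 1) minus each gene's median, had a range of 0.32 over the libraries, against a median of 0.42 for random lists matched on expression (permutation test over genes, 1-sided p = 0.698, adjusted p = 0.722). In 95% of these random lists the range was at most 0.92, so a smaller shared change could have gone unseen. TMM and median-ratio scaling widened the range of the score to 0.58 and 0.60 and moved its lowest value from S13 to S12 and its highest from S20 to S10, with adjusted p of 0.625 and 0.619.

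Most ion channels of the cold sensor list were near or at the limit of detection, and so were most genes of heat production. The list was fixed before the data were examined, and membership does not mean that a channel senses cold. Trpm8, the menthol and cold receptor, had 2 to 14 counts per library and at most 0.0544 FPKM, Trpa1 had 5 counts, all in S10, and Trpc5 had 0 counts in all 6 libraries. A count of 0 allows up to 3 counts, or 0.0507 CPM (counts scaled to library size) in S21 and 0.0750 CPM in S10. Trpm2, a channel of myeloid cells, was the exception in the list, at 6.01 FPKM in S10 and 21.5 FPKM in S23, and Kcnk2 had a median of 1.05 FPKM. The Trpm2 level is not read as that of a cold receptor. Ucp1, the uncoupling protein of brown fat, had 0 counts in all 6 libraries, as did Elovl3 and Cox8b. Ppargc1a and Prdm16 stayed under 0.1 FPKM. Cidea ranged from 0.622 FPKM in S23 to 10.8 FPKM in S12, and Ucp3 had a median of 1.09 FPKM. With 2 members each above a median of 1 FPKM, neither list was tested for spread in the main setting, and without a filter on low genes neither passed (adjusted p = 0.390 for cold sensors and 0.199 for thermogenic genes). Chaperone genes, in contrast, were high: the heat shock list exceeded 99.98% of random lists, with medians of 408 FPKM for Hsp90ab1, 197 FPKM for Hspa8, 169 FPKM for Hspe1 and 152 FPKM for Hspa5, whereas the inducible Hspa1a had a median of 0.422 FPKM. The list member Hspa1b had no row, so the Hspa1a value does not speak for both genes. The heat shock score had a range of 0.34, close to the median of 0.36 of random lists (permutation test over genes, 1-sided p = 0.533, adjusted p = 0.612). In 95% of those lists the range was at most 0.68, which limits the test in the same way.

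**Figure D1:**
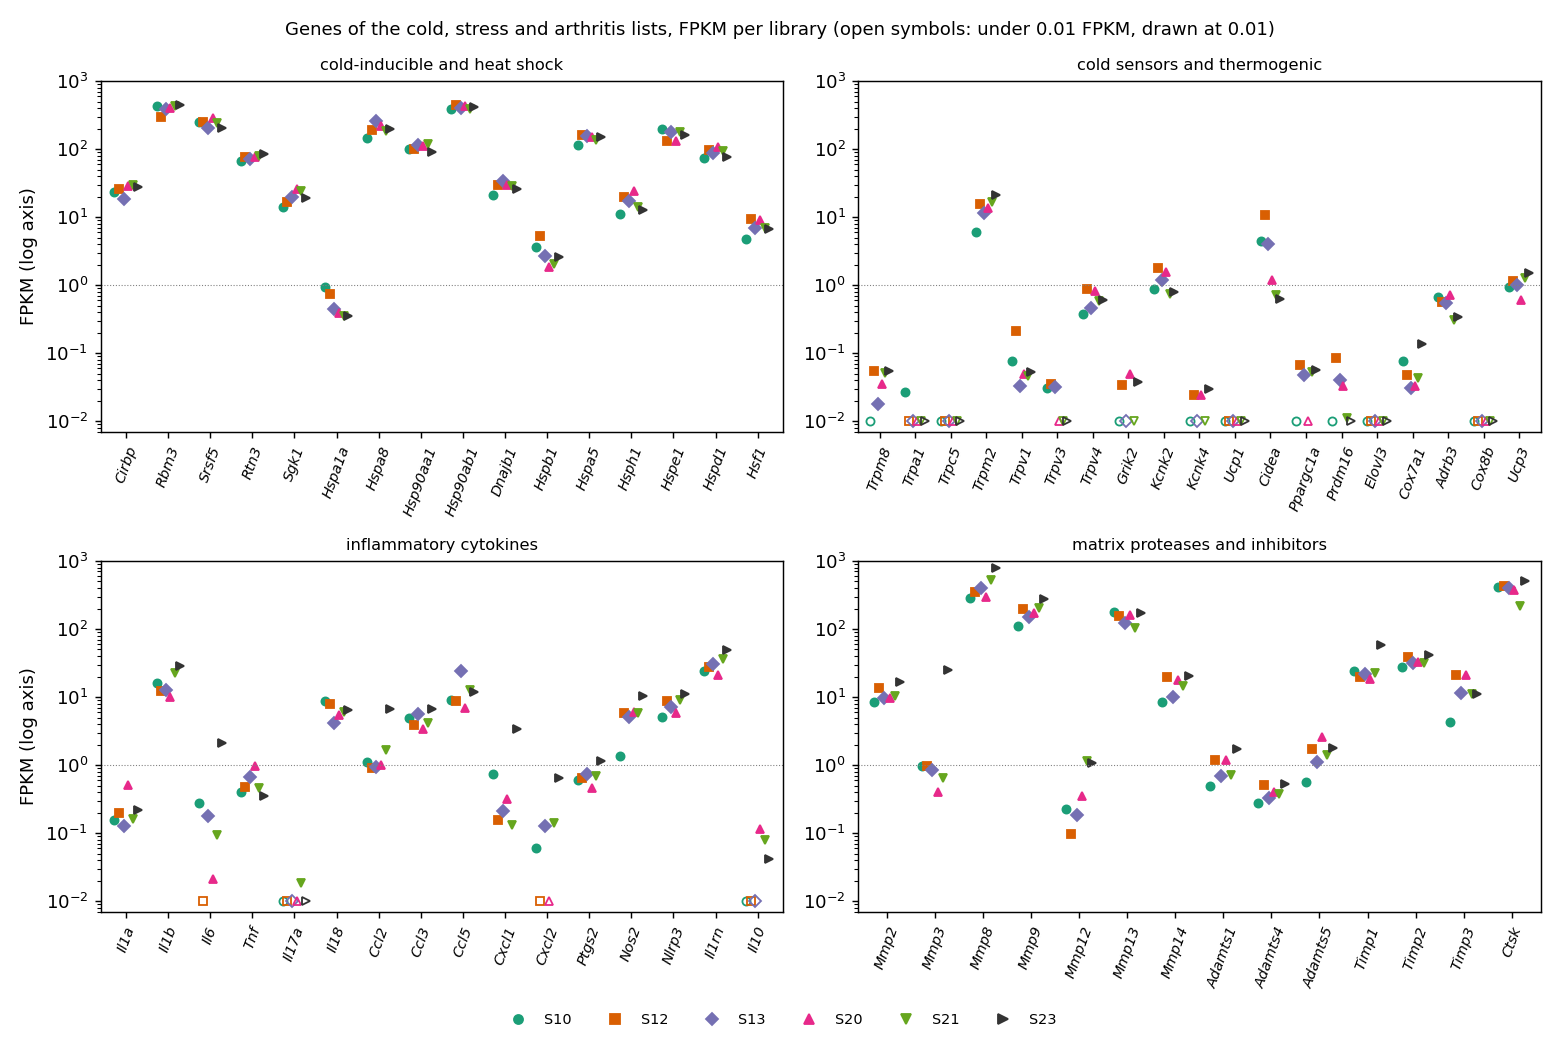
FPKM (log axis) of each member of the cold-inducible, heat shock, cold sensor, thermogenic, inflammatory cytokine and matrix protease lists, with a symbol per library and open symbols for values under 0.01 FPKM. Rbm3 lies between 299 and 437 FPKM in the 6 libraries, Ucp1 has 0 counts in all of them, and Mmp3 reaches 24.9 FPKM in S23 against at most 0.983 FPKM in the other libraries.

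Of the cytokines and proteases tied to arthritis, the proteases were far more abundant. Ctsk (220 to 508 FPKM), Mmp8 (288 to 785 FPKM), Mmp9 (109 to 279 FPKM) and the collagenase Mmp13 (103 to 179 FPKM) had the highest levels of the matrix protease list, and the aggrecan-cleaving Adamts4 and Adamts5 had medians of 0.389 and 1.56 FPKM. The lists overlap: Mmp8 is also in the neutrophil list, and Ctsk and Mmp9 are also in the osteoclast list. Their levels are thus not particular to arthritis. Of 16 cytokine and inflammation genes, 8 had a median of at least 1 FPKM. Il1b (ENSRNOG00000004649) had a median of 14.5 FPKM and 28.3 FPKM in S23, and its antagonist Il1rn ranged from 21.3 to 49.4 FPKM, both lowest in S20 and highest in S23, as was the score of the neutrophil list. Tnf had a median of 0.472 FPKM, and Il17a had 2 counts, both in S21. Il6 had 115 counts in S23 (2.11 FPKM) and 0 to 13 counts in each of the other libraries. S23 had the highest score of both lists. The matrix protease score had a range of 0.89 (permutation test over genes, 1-sided p = 0.0079, adjusted p = 0.0306) and the highest value of 7 of its 10 tested members lay in S23. This call was lost under TMM and median-ratio scaling, with correction for gene length, with a pseudocount of 0.1, with a median score, and without S23, and the adjusted p rose to as much as 0.518. The range was smaller under TMM (0.49) and median-ratio scaling (0.52), after length correction (0.56), with a median score (0.65) and without S23 (0.58), but larger with a pseudocount of 0.1. The cytokine score had a range of 0.96 and missed the threshold (adjusted p = 0.154), with 6 of 8 tested members highest in S23. It passed under 5 of 13 alternatives, among them TMM scaling (adjusted p = 0.0155), median-ratio scaling (0.00682) and leaving out S10 (0.0415), and without S23 its range was 0.50. Bone remodelling signals were low as a list, with a level of 1.99, above 0.46% of random lists. Among its highest members were Tgfb1, Pth1r and Csf1, with medians of 72.8, 15.2 and 6.73 FPKM. Tnfsf11 (RANKL) and Tnfrsf11b (osteoprotegerin), chosen after their values were seen, had medians of 0.779 and 2.39 FPKM. Tnfsf11 had 3 counts in S12 and 6 in S21 (0.0486 and 0.0859 FPKM), and 0.604 to 1.40 FPKM in the other libraries. The range of the bone remodelling score was 0.68 (adjusted p = 0.417), and 0.37, 0.34 and 0.27 under TMM scaling, median-ratio scaling and length correction.

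Muscle, fat, mitochondrially encoded, B cell and neutrophil genes had the widest ranges of the 31 lists. The score of the skeletal muscle list had a range of 3.22, from -1.33 in S20 to 1.89 in S12, and all 9 tested members were highest in S12. With a pseudocount of 0.1 or length correction its lowest value lay in S23, which had -1.28 in the deposited values. Ckm, the creatine kinase of muscle, had 28.1 FPKM in S12 and 0.207 FPKM in S23, and Tnnt3, a troponin, had 22.1 FPKM in S12 and 2.46 FPKM in S20. Adipocyte genes had a range of 2.22 and were also highest in S12, with 6 of 8 tested members highest there. Adipoq (adiponectin) had 62.5 FPKM in S12 and 0.957 FPKM in S23, and Fabp4 had 309 FPKM in S12 and 70.8 FPKM in S20. B cell genes had a range of 1.49, from -0.85 in S21 to 0.64 in S12. Cd79b, part of the B cell receptor, had 83.6 FPKM in S12 and 20.3 FPKM in S23, whereas the pre-B cell genes Igll1 (57.0 FPKM) and Vpreb1 (44.2 FPKM) were highest in S20. The highest B cell score moved to S10 under TMM and median-ratio scaling. Neutrophil genes had a range of 1.39, from -0.58 in S20 to 0.82 in S23, with all 13 tested members highest in S23. The adjusted p was 0.00155 for muscle and adipocyte genes, 0.00310 for B cell genes and 0.00232 for neutrophil genes (permutation test over genes, 1-sided, Benjamini-Hochberg over 31 lists). The test redraws genes, not animals, so it describes these libraries. The neutrophil call was lost without S23 (range 0.79, adjusted p = 0.0818), while muscle, adipocyte and B cell genes passed under all 13 alternatives. Without S12 the range fell to 2.08 for muscle genes and to 1.06 for adipocyte genes (adjusted p = 0.0238).

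A further 5 lists passed the threshold, and the call of each was lost under at least 2 alternatives. Mitochondrially encoded genes had a range of 1.68 (adjusted p = 0.00207), with all 13 members highest in S20 and 11 lowest in S10, and ribosomal protein genes a range of 0.92 (adjusted p = 0.0332) in the opposite order, with 13 of 14 members highest in S10 and 12 lowest in S20. Rps2 had 1809 FPKM in S10 and 655 FPKM in S20. Erythroid genes had a range of 1.15 (adjusted p = 0.00775) and were lowest in S23 for 8 of 11 members. Proliferation genes had a range of 0.99 (adjusted p = 0.0111), with 9 of 10 members highest in S20, where Rrm2 had 114 FPKM against 33.2 FPKM in S10. Interferon-induced genes had a range of 0.91 (adjusted p = 0.0332), with 6 of 12 members highest in S13, where Irf7 had 57.1 FPKM against 18.2 FPKM in S23. All are from the permutation test over genes. Under TMM and median-ratio scaling the calls of mitochondrially encoded genes (adjusted p = 0.196 and 0.221), erythroid genes (0.0949 and 0.111) and proliferation genes (0.625 and 0.638) were lost. The range of the erythroid score did not shrink (1.22 and 1.21), while those of mitochondrially encoded genes (1.12 and 1.12) and proliferation genes (0.53 and 0.51) did, and the range of ribosomal protein genes widened to 1.47 and 1.48. Length correction ended the proliferation call (adjusted p = 0.0688), and a pseudocount of 0.1 those of ribosomal protein genes (0.0579) and interferon-induced genes (0.0800), whose ranges of 0.92 and 1.12 were no smaller than in the main setting. The range of mitochondrially encoded genes was 1.07 without S10 and 1.05 without S20. Leaving out 1 library ended the call of erythroid genes (S23, adjusted p = 0.322, range 0.43), proliferation genes (S10, 0.0952, range 0.58), ribosomal protein genes (S10, 0.0907, range 0.67) and interferon-induced genes (S13, S20 or S23, each in turn, 0.432, 0.293 and 0.0766, ranges 0.57, 0.63 and an unchanged 0.91).

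**Figure D2:**
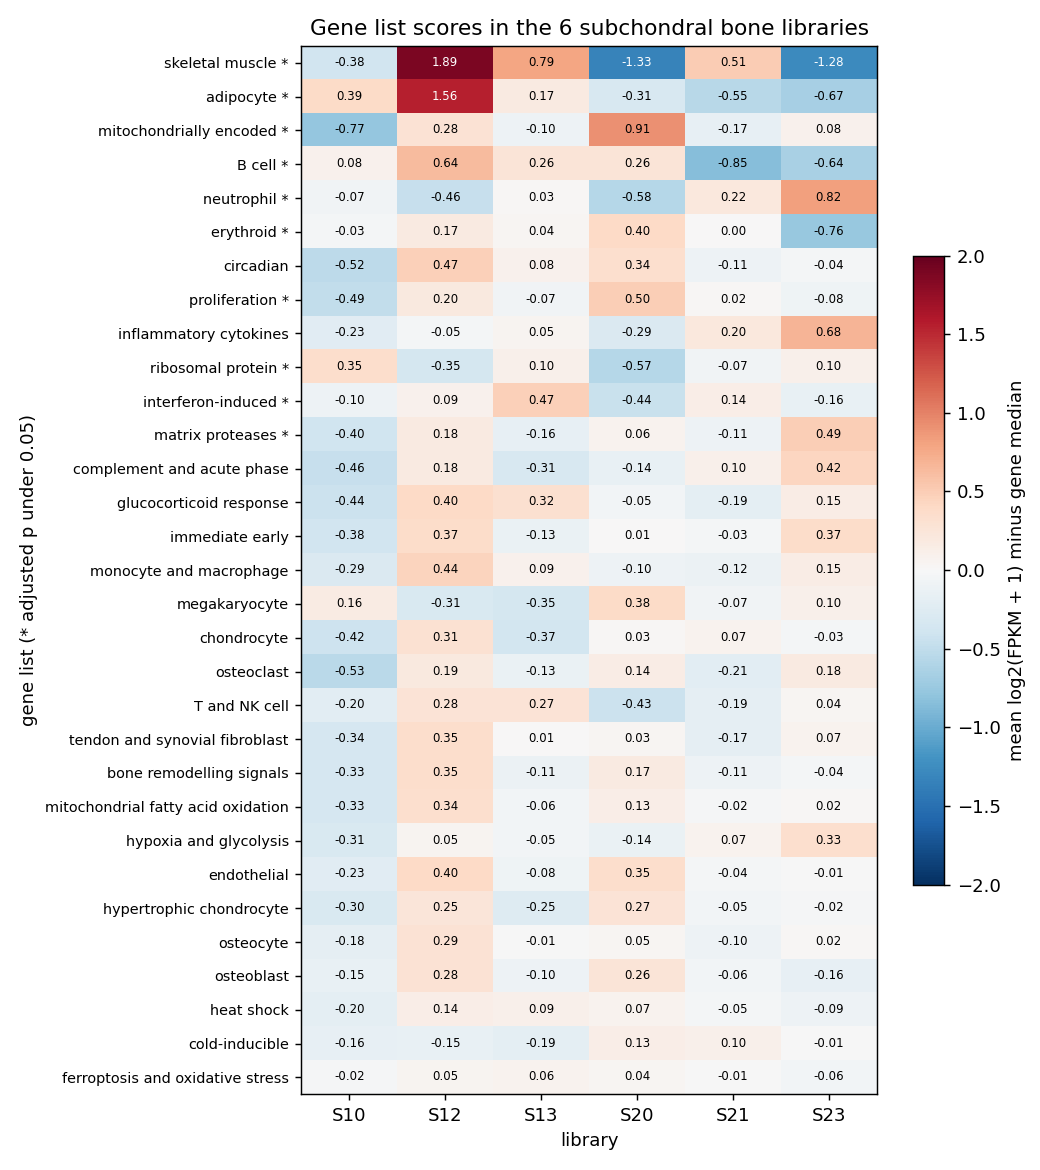
Scores of the 31 gene lists with at least 3 expressed members (rows) in the 6 libraries (columns), as the mean over members of log2(FPKM + 1) minus each gene's median. An asterisk marks the 10 lists with an adjusted p under 0.05. Skeletal muscle genes run from -1.33 in S20 to 1.89 in S12, and cold-inducible genes from -0.19 to 0.13.

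The remaining 21 lists did not pass, among them those of bone and cartilage. The ranges of the osteoblast, osteocyte, osteoclast and chondrocyte scores were 0.44, 0.47, 0.72 and 0.73, with adjusted p of 0.437, 0.711, 0.0999 and 0.193 (permutation test over genes). Under TMM scaling these ranges were 0.44, 0.23, 0.28 and 0.44, under median-ratio scaling 0.44, 0.20, 0.29 and 0.45, and after length correction 0.40, 0.30, 0.43 and 0.44. The lowest osteocyte and chondrocyte scores, in S10 in the deposited values, then lay in other libraries. The osteocyte range was 0.23 without S12 and the osteoclast range 0.40 without S10, and the chondrocyte list passed without S10 (adjusted p = 0.0155). The narrowest range in the deposited values, 0.12, was that of the mean score of the ferroptosis and oxidative stress genes, whose members Fth1, Sod1, Gpx4 and Hmox1 had medians of 1551, 302, 143 and 132 FPKM. Single members were less steady than the score. Gpx4 ranged from 76.7 FPKM in S20 to 290 FPKM in S10, and Hmox1 from 68.8 FPKM in S23 to 199 FPKM in S12. Of 13 members with a row, 6 had a log2 range of at least 1 and 7 a smaller one. The range of the score was 0.53 under TMM scaling, 0.54 under median-ratio scaling and 0.27 after length correction. Genes of the hypoxia and glycolysis list were highest in S23 for 9 of 12 tested members, Ldha with 519 FPKM and Eno1 with 398 FPKM, yet the list's range of 0.64 missed the threshold (adjusted p = 0.212) and was 0.41 without S10 and 0.36 without S23. The glucocorticoid response genes Mt2A, Mt1 and Fkbp5 had medians of 43.4, 35.0 and 32.3 FPKM, the clock gene Dbp 10.4 FPKM, and the fatty acid oxidation genes Hadhb and Hadha 47.0 and 40.1 FPKM. Complement and acute phase genes had a range of 0.88 (adjusted p = 0.0744, and 0.0389 with a median score and 0.0476 without S20). Lcn2, also in the neutrophil list, had 775 to 1704 FPKM, and Hp (haptoglobin) had 134 FPKM in S13 and 864 FPKM in S23. In the immediate early list Junb and Klf4 had medians of 35.2 and 11.2 FPKM.

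The score of 18 of the 31 lists was lowest in S10, and that of 16 was highest in S12. S10 also stood apart by gene length. In S10 the median log2 difference from the gene's median was 0.07 in the fifth of genes with the shortest transcripts and -0.60 in the fifth with the longest, while in S20 these values were -0.20 and 0.34 and in S12 -0.07 and 0.33. Median-ratio scaling moved the median of all genes by 0.39 on the log2 scale in S10 and by -0.24 in S12. After it S10 had the lowest score in 3 lists and the highest in 8, S12 the lowest in 3 and the highest in 8, and S20 the lowest in 11.

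At the level of single genes, 544 of 11625 expressed genes (4.68%) had a range of at least 2 on the log2 scale, a 4-fold difference between the highest and lowest library, and the median gene had a range of 0.83. S10 was the lowest library for 334 of the 544, and without it the count was 225. Among the 20 genes with the largest range were 4 of the list of eosinophil genes that was drawn up after the values were seen. Prg2 (ENSRNOG00000008394), which encodes the major basic protein of eosinophil granules, had 96.0 FPKM in S20 and 1451 to 3958 FPKM in the other libraries. Its relative Prg3 had 5.06 FPKM in S20 against 295 FPKM or more elsewhere, and the ribonuclease genes Rnase3 and Ear1 had 2.79 and 0.792 FPKM in S20 against at least 65.5 and 72.6 FPKM elsewhere. The reverse case was Prss29, a tryptase-type protease gene, with 151 FPKM in S23 and 2.21 to 4.31 FPKM in the other libraries. Thrsp, a gene of fat synthesis, had 89.1 FPKM in S12 and 0.884 FPKM in S23. Rpl35a and Rpl35al1, ribosomal protein genes of near-identical name, were both highest in S13 (82.6 and 126 FPKM) and lowest in S23 (0.938 and 1.12 FPKM), and how reads were divided between them is uncertain. Gp1bb, a platelet receptor gene, had 93.0 FPKM in S10 and 1.69 FPKM in S12. Of the 20 genes, 5 had only clone-based names.

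**Figure D3:**
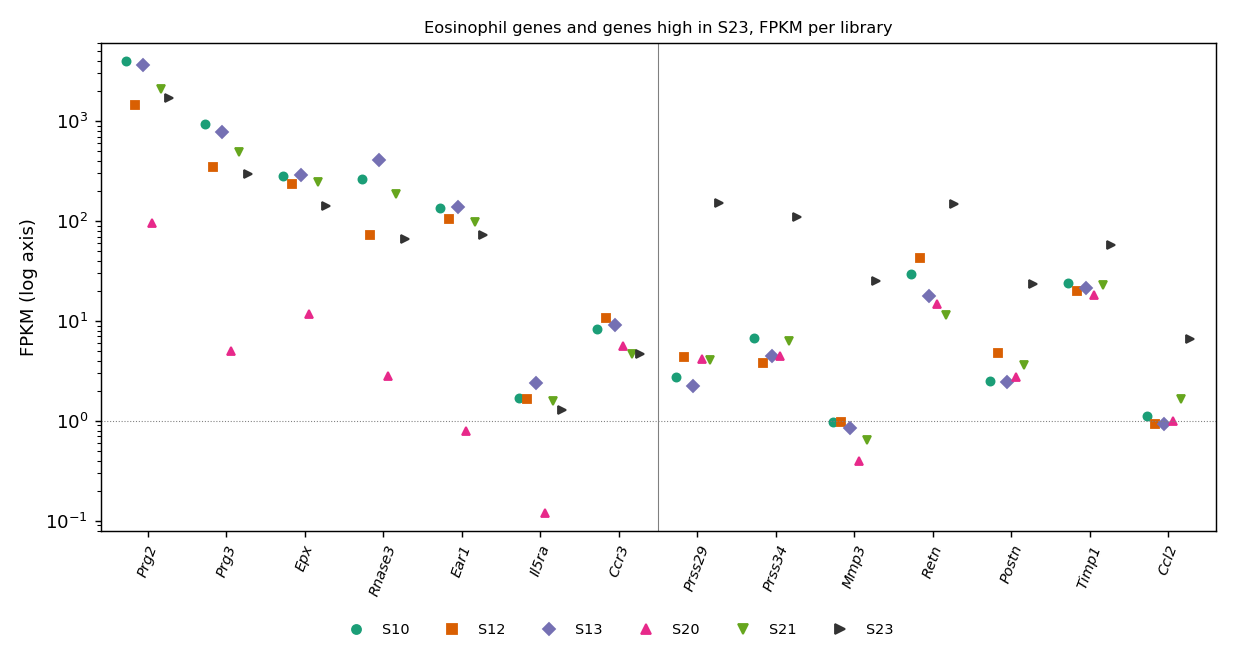
FPKM (log axis) of 7 eosinophil genes and of 7 genes that were high in S23, with a symbol per library. Prg2, Prg3, Epx, Rnase3, Ear1 and Il5ra are lowest in S20, with Prg2 at 96.0 FPKM there, and Prss29 reaches 151 FPKM in S23 against at most 4.31 FPKM in the other libraries.

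Of the 544 variable genes, 26 lay in 2 stretches of neighbouring genes, next to the alpha-globin and the beta-globin genes, with less variable genes such as Snrnp25 and Npm1 among them. Gene order was taken from the rat assembly GRCr8, which is not the build of the deposited values, so no coordinates are given. In the 33 genes from Hbz to Spdl1, next to the alpha-globin genes, each gene with any counts in S12 had at least 21.3 FPKM there, and the lowest values above 0 were 20.1 FPKM in S13 and 2.97 FPKM in S23. In S20 most of these genes had a similar level, but Kcnmb1 had 0.107 FPKM, Kcnip1 0.154 FPKM and Spdl1 12.7 FPKM, and Hbz, Efcab9 and Fgf18, with counts in S12, had 0 counts. The median over all 33 genes was 1.43 FPKM in S10, 25.9 FPKM in S12, 23.5 FPKM in S13, 27.6 FPKM in S20, 7.79 FPKM in S21 and 6.08 FPKM in S23. Il9r, for example, had 28.6 FPKM in S12, 20.1 FPKM in S13 and 0.0743 FPKM in S10, and Stc2 had 22.5, 21.3 and 0.793 FPKM. The 32 genes from Hbg1 to Cyb5r2, next to the beta-globin genes, had another order of libraries, with medians of 6.15 FPKM in S10, 5.69 FPKM in S13 and 5.15 FPKM in S21 and of at most 1.85 FPKM in S12, S20 and S23. Dnhd1, for example, had 5.28 FPKM in S10, 5.21 FPKM in S13, 4.42 FPKM in S21 and 0.364 FPKM in S23. Dusp1, an immediate early gene, lies in the first stretch.

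**Figure D4:**
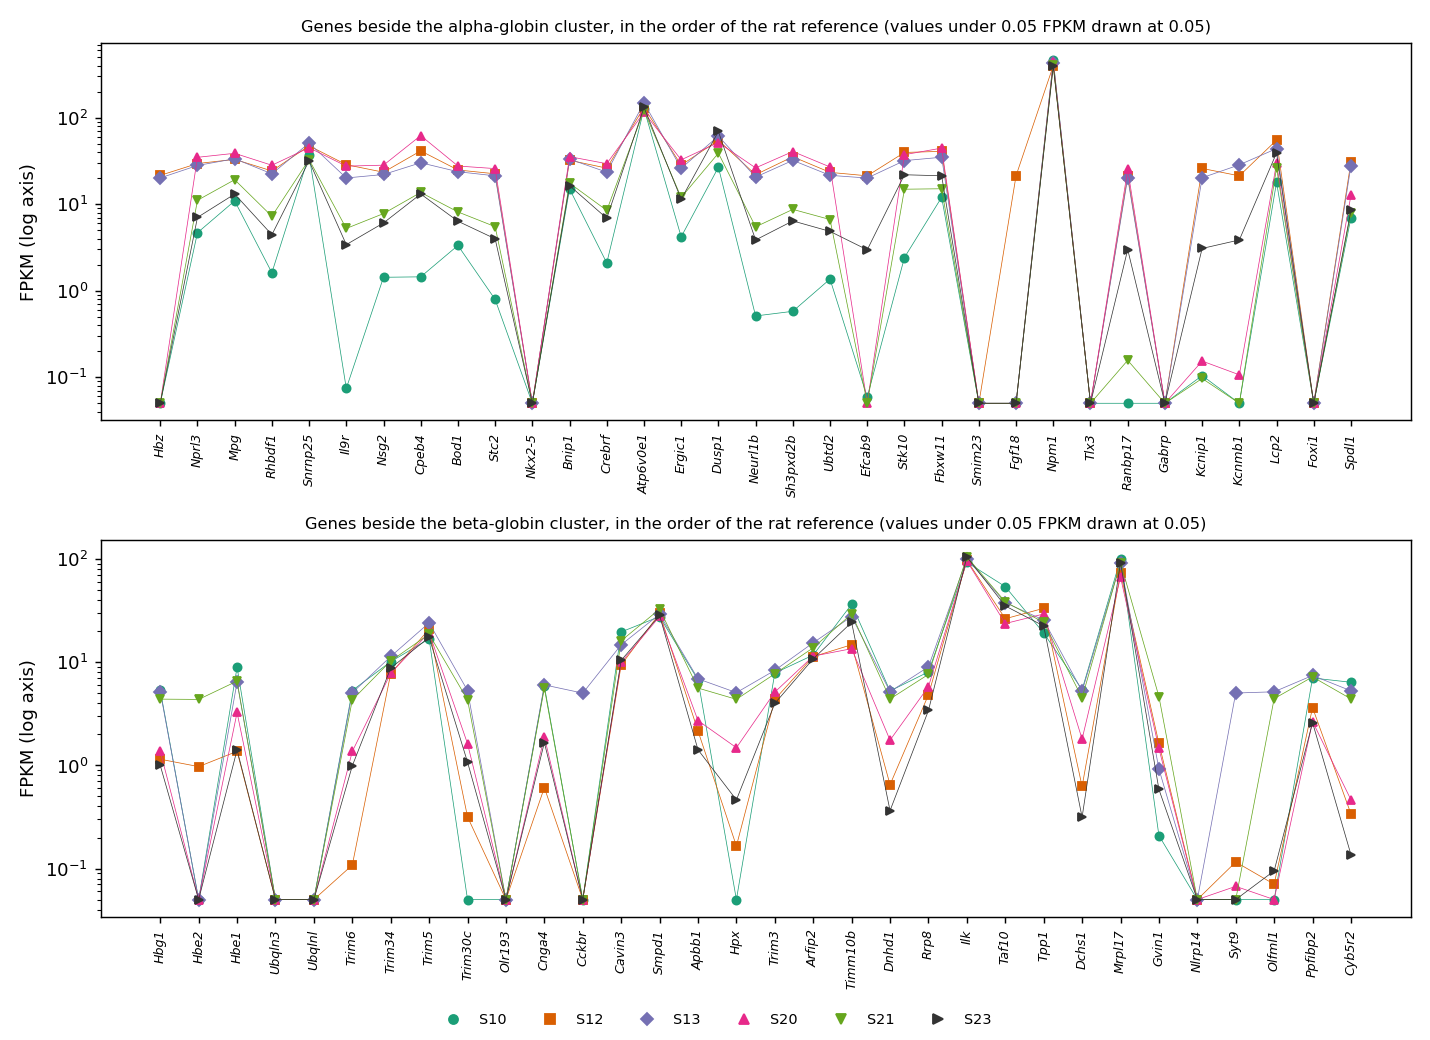
FPKM (log axis) of the genes next to the alpha-globin cluster (upper panel, 33 genes) and the beta-globin cluster (lower panel, 32 genes), in the gene order of GRCr8, with a line per library and values under 0.05 FPKM drawn at 0.05. In S12 the genes with counts in the upper panel do not fall under 21.3 FPKM, while in S10 Ranbp17 has 0.0482 FPKM.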

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

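The tests in this part were chosen after the patterns were seen. Signal outside the main measurement came from the 8550 loci without annotation, which held a median of 2.55% of all counts and at most 2.92% in any library. Of these loci 1073 had a median of at least 1 FPKM, and the highest, Rattus_norvegicus_newGene_2260, had a median of 1404 FPKM and 0.325% of counts.

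The eosinophil granule genes were far lower in S20 than in any other library, though still detected. Prg2, Prg3, Epx, Rnase3, Ear1 and Il5ra were each lowest there, with Epx at 11.7 FPKM against 142 to 290 FPKM elsewhere, while Ccr3, a chemokine receptor of mature eosinophils, had 5.59 FPKM in S20 and 4.72 to 10.7 FPKM elsewhere. A loss of all granulocytes to the same degree would lower neutrophil genes alike, but their median log2 difference of S20 from the other libraries was -0.41 against -4.42 for the 7 eosinophil genes. The trend with gene length is argued against as well, since the eosinophil median was -4.45 after its removal. No effect of temperature was tested, because the labels give no group, and a smaller share of eosinophil precursors in S20 stays open.

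Transcript levels in S10 fell with gene length. Spearman's rho between a gene's log2 difference from its median and its length was -0.51 in S10, 0.48 in S12 and 0.55 in S20 across genes, which are not independent replicates. Cell makeup alone is argued against, because the correlation was negative in S10 within 30 of 31 gene lists and in S12 and S20 within 3 of 31. Depth is argued against by S20, whose total count is close to that of S10 and whose rho was 0.55. Shorter or more degraded RNA in S10 may be the cause, but that cannot be told apart here (rho = -0.51), because read coverage along transcripts was not analysed here, and no biological explanation was tested.

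The shared level of genes next to the globin clusters was a further pattern. Chance clustering is argued against: the highest median range of 11 neighbouring genes was 4.48 on the log2 scale, against at most 2.14 in 200 random gene orders, and of 29 windows above that, 23 centred on the first stretch, 5 on the second and 1 just outside. A constant FPKM added to each gene of a stretch that has reads would leave none of these genes under that level. Next to the alpha-globin genes 5 values with reads lay under 1 FPKM outside S10. They were those of Kcnmb1 and Kcnip1 in S20 (0.107 and 0.154 FPKM) and of Kcnmb1, Kcnip1 and Ranbp17 in S21 (0.0188, 0.0967 and 0.157 FPKM). In S20 and S21 a constant was thus not added to every gene with reads. In S12, S13 and S23 no value with reads lay under 1 FPKM. There, and for the other genes of S20 and S21, a constant cannot be told apart from other causes. An addition in proportion to alpha-globin is argued against, since S10 had the highest alpha-globin level (329223 FPKM) and a median of 1.85 FPKM over all 28 genes of the stretch with a count in any library, while S23, with the lowest (115873 FPKM), had 6.64 FPKM and exceeded S10 in 24 of the 28. In each stretch some genes had no counts in any library (5 of 33 and 4 of 32), and no biological explanation was tested.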

How the results depend on the processing

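Correction for gene length, leaving out the genes next to the globin clusters and the 2 added lists were chosen after the data were seen. The number of lists past the threshold, 10, stayed between 7 and 12 under the settings that kept all libraries and between 6 (without S23) and 11 (without S20) when a library was left out. It was 9 after length correction, and the 2 added lists were not counted, because they were drawn up after the spread of members was seen. TMM and median-ratio scaling ended 4 calls each and brought 2 and 3 new ones. They moved the median of all genes by 0.39 in S10 on the log2 scale under both, by -0.21 and -0.24 in S12, by -0.16 and -0.17 in S20 and by -0.11 under both in S23. The count of variable genes, 544, was 1281 with a pseudocount of 0.1, which lets low genes vary more, and 225 (without S10) to 517 (without S21) when a library was left out. It was 373 after length correction and 518 without the genes next to the globin clusters. The median number of rows at 5 FPKM or more was 8165, lower than at 1 FPKM by construction. The 10 most abundant rows held 22.5% of FPKM without the 4 named globin rows. The median correlation between libraries was 0.758 over the 1000 most variable genes, which were chosen for their spread. Of the 24 list correlations, 6 were below 0, against 10 with median-ratio scaling and 12 without the 2 libraries farthest from the median, and the cause was not tested. With 4 libraries no p was computed. No list correlation passed the adjusted threshold under any setting with 6 libraries. By rho a single perfect pair could not pass: the osteoclast list with the tendon and synovial fibroblast list had rho = 1 (exact permutation p = 0.00278, adjusted p = 0.0667). The level of 5 of 35 lists moved beyond its range over libraries with a pseudocount of 0.1 and that of 4 of 31 with expressed members only. The log2 range of 62 of 225 named genes moved by more than its spread with median-ratio scaling, and that of 44 with a pseudocount of 0.1. No paired analysis was possible because the labels form no groups. The planned check of a comparison by the authors gave no value, since the table used here holds only counts and FPKM. Depth limits genes such as Trpm8 and Il17a, with 51 and 2 counts in all.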

Other observations

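The test of the bone lists was planned, its prediction was put in numbers after the data were seen, and the lists and genes of the next paragraph were chosen after their values were seen.

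S23 had the highest level of several genes that come from no single fixed list. Prss34, a basophil protease gene, had 110 FPKM in S23 against at most 6.83 FPKM in the other libraries, and the stromelysin Mmp3 had 24.9 FPKM against at most 0.983 FPKM. The basophil and mast cell list, of which Prss34 is 1 of 11 members, had a score range of 0.74. In 95% of matched random lists the range was at most 0.87. In S23 7 of the 11 members were highest, some narrowly, such as Mcpt8l2 (374 FPKM against 369 FPKM in S10). Cma1 was lowest there (10.7 FPKM). Resistin (Retn) had 148 FPKM against at most 42.2 FPKM, the matrix genes Postn and Col3a1 had 23.5 and 48.1 FPKM against at most 4.76 and 24.6 FPKM, and Gal, the galanin gene, had 11.5 FPKM against at most 2.23 FPKM. Timp1 had 57.3 FPKM against at most 24.2 FPKM, and Ccl2 and Cxcl1 had 6.61 and 3.36 FPKM against at most 1.67 and 0.734 FPKM. The tendon and synovial fibroblast score, in contrast, was 0.07 in S23 and 0.35 in S12, and Col1a1 had 183 FPKM in S23 and 362 FPKM in S12. The eosinophil list, which was drawn up after the spread of members was seen, so that a test of it would be circular, had scores of 0.63 in S10, -0.10 in S12, 0.73 in S13, -3.84 in S20, 0.08 in S21 and -0.47 in S23. Alox15, an enzyme of eosinophils and macrophages, had 235 FPKM in S20, its highest value. Ikzf1, a transcription factor gene of lymphoid development, had 4.03 FPKM in S10 and 16.3 to 38.1 FPKM in the others.

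Whether the libraries fall into separate clusters was not tested. Spearman's correlation across expressed genes was between 0.901 (S10 with S20) and 0.975 (S13 with S21, and S21 with S23), and the mean of a library's 5 correlations was 0.932 for S10, 0.953 for S12, 0.962 for S13, 0.942 for S20, 0.964 for S21 and 0.953 for S23. The first principal component held 56.8% of the variance, and 41.8% after length correction, and Spearman's rho between its gene weights and gene length was -0.581. Its values were 58.3 for S10, 7.06 for S21, 4.79 for S13, -5.29 for S23, -31.0 for S12 and -33.9 for S20. The second held 18.4%, with S23 at 32.7, S21 at 6.62, S13 at 1.07, S12 at -4.75, S10 at -13.4 and S20 at -22.3.

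A hypothesis held that the libraries differ in how much muscle, marrow, fat or soft tissue came with the bone, which would set bone lists against those lists. Over the 6 libraries, 6 of 24 pairs had r below 0, and 0 of 24 had r below 0 with an adjusted p under 0.05 (exact permutation test over pairings, 2-sided). At an unadjusted 0.05, 2 pairs passed by r, both positive: the tendon and synovial fibroblast list with the osteocyte list (r = 0.98, exact permutation p = 0.00417, adjusted p = 0.0833, rho = 0.943, exact permutation p = 0.0167) and with the osteoclast list (r = 0.888, exact permutation p = 0.00694, adjusted p = 0.0833, rho = 1, exact permutation p = 0.00278). By rho the osteoblast and erythroid lists passed as well (rho = 0.886, exact permutation p = 0.0333, adjusted p = 0.267). Without S10 and S12, the 2 libraries farthest from the median of the tendon and synovial fibroblast list, r was 0.947 and 0.828. The tendon and synovial fibroblast, osteocyte and osteoclast scores were all lowest in S10 and highest in S12, the libraries that scaling shifted most. Their ranges were 0.69, 0.47 and 0.72, and 0.29, 0.23 and 0.28 under TMM scaling. A shift shared by all genes of a library can make such pairs positive. With the 2 libraries farthest by the adipocyte list left out, all 4 adipocyte pairs turned from positive to negative (osteoblast 0.49 to -0.545, osteocyte 0.593 to -0.388, osteoclast 0.0442 to -0.597, chondrocyte 0.23 to -0.978). All 4 pairs with the neutrophil list were negative, in the direction of the hypothesis: r = -0.807 with the osteoblast list (exact permutation p = 0.0542, adjusted p = 0.433), and -0.37, -0.22 and -0.05 with the osteocyte, chondrocyte and osteoclast lists. With 6 libraries, which may not form a single cluster, the hypothesis stays undecided.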
